A study of Mus musculus with 18 samples.

How the data were processed

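Per the labels, total RNA came from the middle of 3 parts of mouse embryos at embryonic day 9.5 that were wild type, heterozygous or homozygous mutant for Nkx2-5, also called Csx. Each of the 3 genotypes was measured on 3 arrays of each of 2 array types, 18 arrays in all. The array types carry different probe sets and are called type a and type b here, after the letter in the labels. Replicates carry the numbers of the labels: 1, 5 and 7 for wild type, 3, 4 and 8 for heterozygous, and 2 and 6 for homozygous mutant on both types. The remaining homozygous mutant array is numbered 8 on type a and 9 on type b, and the labels do not say whether both hold the same RNA. These arrays are called 8a and 9b, and their values stand side by side only where a value per replicate is described. The labels do not say whether an array holds 1 embryo or a pool, or whether embryos shared a litter, and give no somite stage, so a difference in stage between genotypes was not tested. The p-values of single probe sets therefore measure only the spread between these samples, which may be technical.

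The deposited values are intensity per probe set, a group of oligonucleotide probes that is read as 1 value and can match more than 1 gene. The values show a linear scale with background subtracted, since 13.5% to 18.4% of the values on type a arrays and 25.6% to 27.7% on type b arrays were negative. The array software, its background correction and the scaling target used by the authors are not given in the sources used here, so how the deposited intensity was scaled was read from the values alone. No centring of genes was seen, and direction does not arise with 1 colour. The median intensity on type a was 526.8, 561.4 and 494.6 for wild type 1, 5 and 7. It was 567.0, 571.3 and 540.2 for heterozygous 3, 4 and 8, and 548.8, 519.7 and 472.6 for homozygous mutant 2, 6 and 8a. On type b the medians were 286.5, 317.4 and 269.4 for wild type 1, 5 and 7, then 338.0, 324.5 and 354.6 for heterozygous 3, 4 and 8. They were 286.4, 335.0 and 271.8 for homozygous mutant 2, 6 and 9b. The mean after trimming 2% was close to 1502 on every type a array, and over the probe sets with a value on every array the trimmed means differed by at most 0.0491% on type a and 0.774% on type b. The authors' scaling was therefore kept, since a limit of 1% had been set. Heterozygous array 8 of type b had no value for 499 probe sets. Over the probe sets it has, its trimmed mean was 1649.3, against 1503.2 to 1503.9 on the other type b arrays.

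Control probe sets were left out, 61 on each type (55 with the maker's control prefix and 6 of yeast), which left 13057 probe sets. Gene symbols came from the platform annotation, updated through gene identifiers: 5551 of 5560 identifiers matched on type a and 1993 of 2001 on type b. Of the probe sets 7542 had 1 symbol, 224 had several and 5291 had none, and only those with 1 symbol are named. Whether a named probe set also takes up signal from related genes was not tested. No probe set carried the symbol Nkx2-5, so the level of the mutated gene was not analysed here and the genotype labels were not checked through it.

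A floor was set for each array type at 2 times the noise SD. The noise SD was the scaled median size of the negative values, 187.5 on type a and 261.5 on type b, and the floors were 375.1 and 523.1. Values under the floor were set to it and log2 was taken. A log2 fold change next to the floor understates the change, and where all arrays of a group lay under the floor the fold is a lower bound, written as at least N-fold. A probe set was tested when it exceeded the floor on at least 3 of the 9 arrays, which 3969 probe sets did on type a and 2966 on type b, 6935 together. They held 4631 probe sets with 1 symbol, for 3909 genes. The number of arrays, 3 per genotype and type, limits the precision.

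Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided). The fit was made for each array type on its 9 arrays, with all genotypes sharing the estimate of spread, and Benjamini-Hochberg adjustment ran over both types together. An adjusted p under 0.05 counted as a change. The comparisons were homozygous mutant with wild type, heterozygous with wild type, homozygous mutant with heterozygous, and heterozygous with the midpoint of the other genotypes. The same 9 arrays enter every comparison, so comparisons that share a genotype share its chance values.

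Gene lists, 28 in all, were tested with limma's cameraPR at a preset correlation between genes of 0.01, using for each gene the probe set of highest mean level. This test sets the genes of a list against the other tested genes, with genes as the unit. Its p-value therefore does not measure how far a list varies between replicates, and can be very small with 3 replicates per genotype. Other probe sets of a gene can differ, and for genes named for a change or for a small unadjusted p they are given where the sign or the call differs. The lists with at least 5 tested genes, 24 of them, were adjusted together. They covered cardiac sarcomere, genes reported lower in Nkx2-5 null hearts, cardiac transcription factors, heart field progenitors, calcium handling and conduction, endothelium, primitive erythroid cells, neural tube, neural crest, somite and skeletal muscle, and liver bud and visceral endoderm. They also covered gut and surface epithelium, mesenchyme of limb, body wall and cushion, Hox genes by paralogue in 3 lists, glycolysis and hypoxia response, oxidative phosphorylation, cell cycle, p53 targets and apoptosis, and immediate early and heat shock genes. The last were Bmp and Tgf-beta signalling, imprinted growth genes and cytosolic ribosomal proteins. Smooth muscle, myeloid and platelet, trophoblast and decidua, and sex-linked lists had too few tested genes. The set test was repeated with a correlation estimated from the residuals for each list.

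The comparisons, tests, thresholds, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 probe sets of largest fold in each direction among those past the threshold whose groups do not overlap, or 5 in the comparisons other than homozygous mutant with wild type. Where fewer than 5 passed, the list was filled to 5 by smallest unadjusted p, as values. It adds from each list up to 4 members past the threshold, or 3 members of a list that passed without any, and the 4 members of highest level from the sarcomere, reported lower and erythroid lists. Any other gene given was chosen after its values were seen.

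The steps were tested on simulated data for the comparison of homozygous mutant with wild type, where 7864 probe sets were tested. Of 100 probe sets changed 2-fold, 32 were recovered, and of 100 changed 4-fold, 68 were, all in the right direction. Of 108 called, 8 had not been changed, and none was called when no change was simulated. A list of 22 genes shifted by 0.5 on the log2 scale was found with an adjusted p of 3.56e-13, and none of the other lists passed. The simulated values were drawn independently for each probe set and array, without correlation between genes or likeness between replicates. They therefore cannot show how often a list passes by chance in the real samples. Alternatives covered quantile normalization, scaling to the 75th percentile, a floor at other heights, other filters, other variance models, array weights, a fit on only the groups compared, adjustment within array types, each replicate left out, and other set tests. Added after the data were seen were a fit without arrays 8a and 9b, a block for the replicates with high Afp signal, a block for clusters of replicates, and the alternatives for the lists and named genes of the later comparisons.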

Results

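Gene expression was measured in the middle of 3 parts of mouse embryos at embryonic day 9.5. The tissue was not separated further and expressed genes of heart, nerve, blood and gut together. Embryos were wild type, heterozygous or homozygous mutant for Nkx2-5, a homeobox transcription factor of the early heart that is linked to congenital heart disease. Each genotype had 3 replicates on each of 2 array types, and 6935 probe sets for 3909 named genes were bright enough to be tested. Between 54.5% and 57.8% of the probe sets on type a arrays and between 38.6% and 44.0% on type b arrays exceeded the floor of intensity. The 44.0% is that of heterozygous 8, which lacks 499 values and was counted over those it has. The other type b arrays had at most 42.7%. The Spearman correlation of levels between arrays, across genes that are not independent replicates, was 0.876 to 0.973 on type a and 0.845 to 0.963 on type b.

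No probe set was annotated to Nkx2-5, so the mutated gene itself could not be read out and the genotypes are those of the labels. Homozygous mutant arrays 8a and 9b differed from every other array of their type in control signals. The 3' to 5' ratio of actin, a sign of shortened RNA, was 2.5 on array 8a against 0.967 to 1.41 on the others, and 2.28 on array 9b against 0.849 to 1.4. The BioB spike-in, a bacterial transcript added in a fixed amount, had a mean intensity of 3950 on array 8a and 4531 on array 9b, with at most 1539 and 2320 on the others. Afp, which marks liver bud and visceral endoderm, was high in 1 replicate of each genotype: 1257 to 1775 on type a and 3309 to 3642 on type b in wild type 1, heterozygous 4 and homozygous mutant 2. In the other replicates Afp was 90.6 to 233.8 and 336.7 to 705.9.

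**Figure D1:**
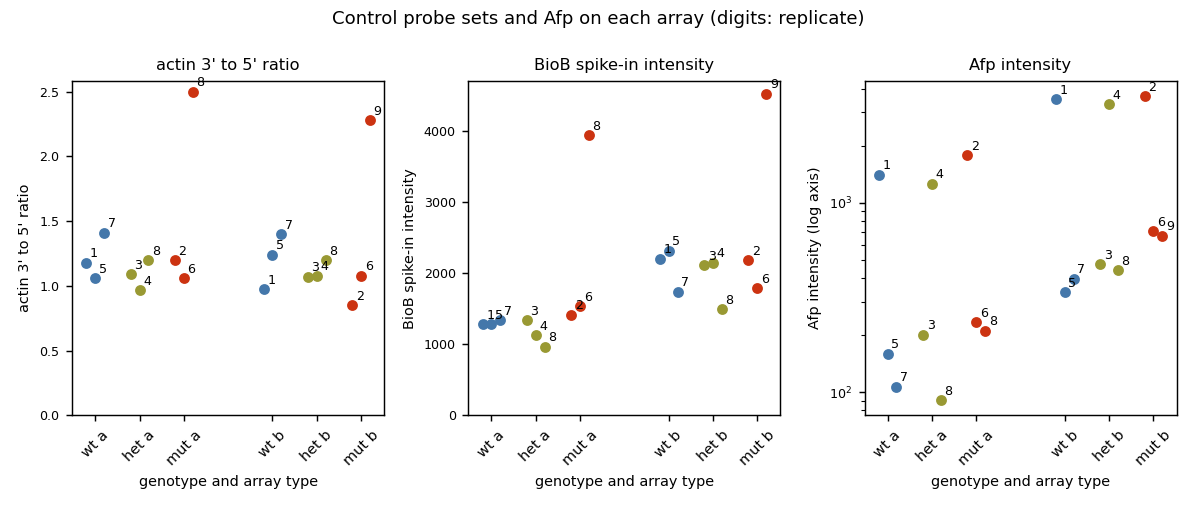
Actin 3' to 5' ratio, BioB spike-in intensity and Afp intensity (log axis) on each array, by genotype (wt wild type, het heterozygous, mut homozygous mutant) and array type (a, b), with the replicate number beside each point. Homozygous mutant 8 of type a and 9 of type b lie above all others of their type for actin (2.5 and 2.28) and BioB (3950 and 4531), and Afp is high in wild type 1, heterozygous 4 and homozygous mutant 2.

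Loss of both Nkx2-5 alleles was compared with wild type, 3 against 3 replicates. The glycolysis and hypoxia list rose in the homozygous mutants, with 7 of its 21 tested genes past the threshold. Ddit4, a stress-induced inhibitor of mTORC1, rose 10.2-fold, from an intensity of 2348 ± 233 (SD, n = 3) to 23880 ± 2590, with a log2 fold change of 3.35 (SE 0.209, limma adjusted p = 3.67e-05). Slc2a3, a glucose transporter, rose 4.24-fold from 3038 ± 494 to 12780 ± 950 (adjusted p = 0.00015), and its other probe set rose 5.4-fold (adjusted p = 0.0189). Pdk1, a kinase that holds pyruvate out of the mitochondrial citrate cycle, rose 2.9-fold from 1268 ± 226 to 3669 ± 579 (adjusted p = 0.00783). Adm, the vasodilator peptide adrenomedullin, was under the floor in every wild type and rose at least 3.41-fold to 1316 ± 372 (adjusted p = 0.00534).

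Of the 21 tested genes of the glycolysis and hypoxia list 7 rose, none fell and 14 did not pass over all genes. Adjusted over the list alone 14 were higher. All 21 had a positive log2 fold change, with a median of 0.89, and the list passed at an adjusted p of 5.26e-39 and at 3.87e-28 with an estimated correlation. The list's median deviation from wild type was 1.05, 1.08 and 0.91 in homozygous mutants 2, 6 and the pair 8a and 9b, against a range of -0.15 to 0.03 in wild type and heterozygous replicates. After quantile normalization it was 1.07, 1.07 and 0.49 in the mutants. The other members past the threshold, named after their values were seen, were the collagen prolyl hydroxylases P4ha2 (log2 fold change 1.44, adjusted p = 0.0152) and P4ha1 (1.37, adjusted p = 0.0123), and Ndrg1 (1.19, adjusted p = 0.00783). No enzyme of glycolysis passed at its brightest probe set, with log2 fold changes from 0.10 for Gapdh (SE 0.403) and 0.35 for Ldha (SE 0.312) to 0.89 for Hk2 (SE 0.292) and 0.91 for Pfkl (SE 0.224). Aldoa and Tpi1 rose at a less bright probe set (0.86, adjusted p = 0.0199, and 0.85, adjusted p = 0.0190), also named after their values were seen, and had 0.34 and 0.50 at the brightest. Among the replicates with high Afp the list's median was 0.92, and among the others it was 0.85.

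**Figure D2:**
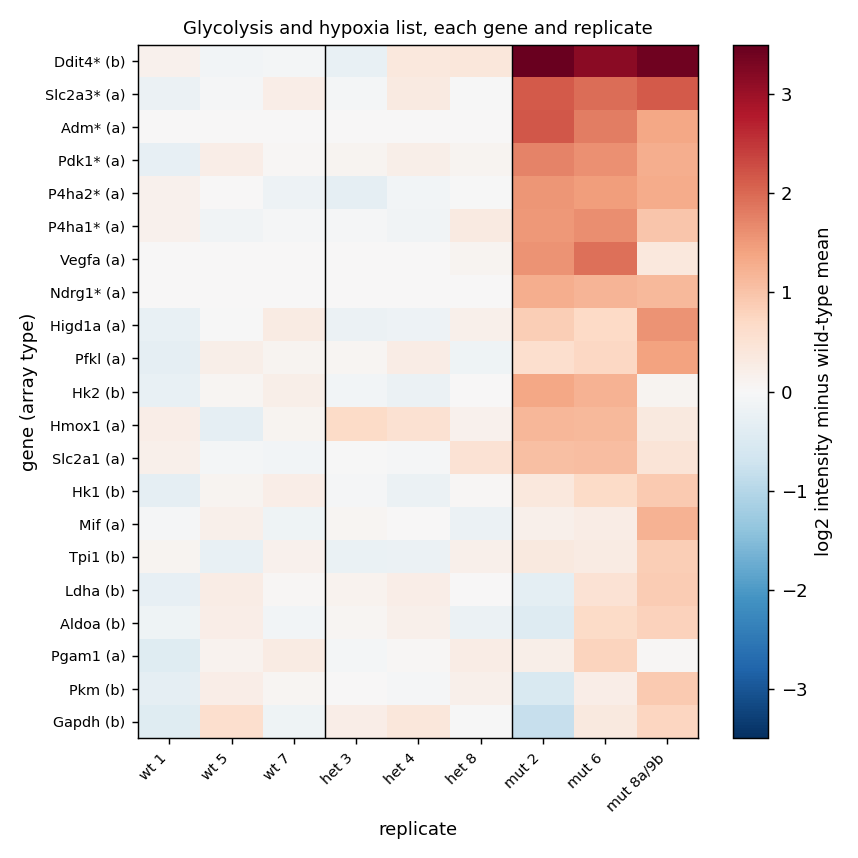
Log2 intensity minus the wild-type mean (colour) for each gene of the glycolysis and hypoxia list (vertical axis, array type in brackets, asterisk for an adjusted p under the threshold) in each replicate (horizontal axis). Ddit4 shows the highest values in the homozygous mutants (log2 fold change 3.35), and the median over the 21 genes is 0.89.

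Over all genes 48 probe sets changed, 35 higher and 13 lower, for 25 named genes higher and 11 lower. At an unadjusted p under 0.05 there were 777, where chance gives 346.8. In all 48 the wild-type and mutant values did not overlap, as in 15.4% of the tested probe sets against at most 10% by chance. That share holds without ties, and values set to the floor tie, which lowers it. Ier3, an immediate early gene, was under the floor in wild type (194.2 ± 224) and rose at least 6.72-fold to 3595 ± 932 (adjusted p = 0.000629). Krt19, a keratin of simple epithelia, rose 5.22-fold from 734.0 ± 170 to 3763 ± 262 (adjusted p = 0.00141). Vldlr, a receptor for lipoproteins, rose at least 3.9-fold to 1471 ± 189 (adjusted p = 0.000629). Apoe, an apolipoprotein, rose at least 4.6-fold (adjusted p = 0.0313) with a wide spread in the mutants (2077 ± 1590), and its brighter probe set had a log2 fold change of 2.19 (adjusted p = 0.122). Ndrg2, a member of the Ndrg1 family, rose 3.9-fold (adjusted p = 0.0190), although in wild type only 1 of 3 arrays exceeded the floor.

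Ckb, the brain-type creatine kinase, fell from 9446 ± 2790 to 3593 ± 290, a log2 fold change of -1.36 (SE 0.205, adjusted p = 0.0111). Its brighter probe set had -1.32 (adjusted p = 0.119). Srsf6, a splicing factor, fell by 1.31 on the log2 scale (adjusted p = 0.00783), and its other probe set, about as bright, had -0.61 (adjusted p = 0.111). Hcfc1, a transcriptional coregulator, fell at least 2.73-fold, to under the floor in every mutant (adjusted p = 0.0217). Bysl, a factor of small ribosomal subunit assembly, fell by 1.29 (adjusted p = 0.0219). Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, fell by 1.0 (adjusted p = 0.0217), and its brighter probe set had -1.19 (adjusted p = 0.0709). Rrm2, a subunit of ribonucleotide reductase, fell by 0.94 at 1 probe set (adjusted p = 0.0190) and had -0.47 (adjusted p = 0.326), -1.11 (adjusted p = 0.225) and -0.46 (adjusted p = 0.654) at the others, the first of these the brightest. Mrpl20, of the mitochondrial ribosome, fell by 0.99 (adjusted p = 0.0191), and Idh1, the cytosolic isocitrate dehydrogenase, fell by 0.85 (adjusted p = 0.0191). Txnrd1, a thioredoxin reductase, fell by 0.82 (adjusted p = 0.0440), and Nnat, the imprinted neuronatin, fell from 10540 ± 1700 to 6041 ± 335 (adjusted p = 0.0313).

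**Figure D3:**
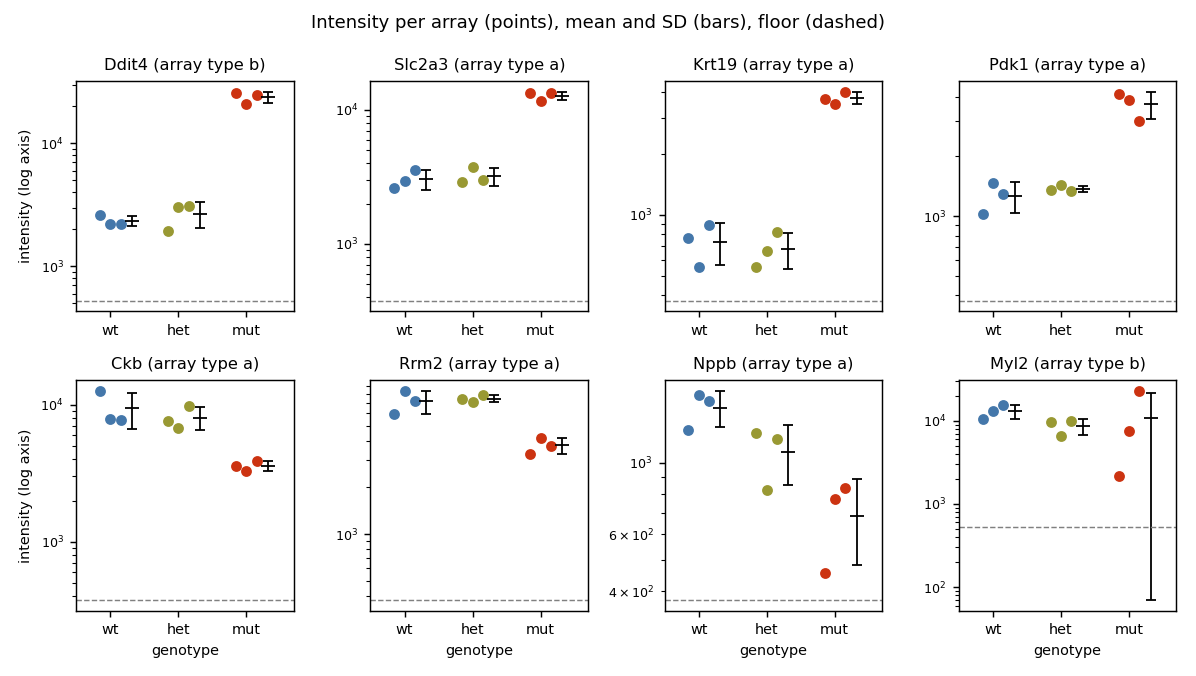
Intensity on a log axis for Ddit4, Slc2a3, Krt19, Pdk1, Ckb, Rrm2, Nppb and Myl2 by genotype (wt wild type, het heterozygous, mut homozygous mutant). Points are arrays, bars are mean and SD with n = 3, and the dashed line is the floor (375.1 on type a, 523.1 on type b). Mutant means were 23880 for Ddit4 and 3593 for Ckb, and Myl2 spans 2169 to 22957 within the mutants.

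Heart genes did not pass the test. None of the 12 sarcomere genes passed, over all genes or adjusted over the list alone. The median log2 fold change of that list was 0.03 and its mean was -0.11, which differ in sign, with an adjusted p of 0.646. Actc1, cardiac actin, had 65760 ± 15500 in wild type and 61320 ± 14400 in the mutants (log2 fold change -0.10, adjusted p = 0.928), and its other probe set had 0.14 (adjusted p = 0.899). Log2 fold changes were 0.06 for Myl4 (SE 0.343), 0.21 for Tnnc1 (SE 0.349) and 0.12 for Myh6 (SE 0.419), and each was negative without arrays 8a and 9b (-0.32, -0.09 and -0.30). The sarcomere list's deviation was -0.58 and -0.04 in homozygous mutants 2 and 6 and 0.80 on arrays 8a and 9b, the arrays with the raised actin ratio. Myl2, the ventricular myosin light chain, had 2169 in homozygous mutant 2, 7483 in 6 and 22957 in 9b, against 13000 ± 2360 in wild type (log2 fold change -0.84, SE 0.624, adjusted p = 0.681).

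Of the 6 tested genes reported lower in Nkx2-5 null hearts none passed over all genes, and 1 was lower adjusted over the list alone. That gene was Nppb, the B-type natriuretic peptide, with 1477 ± 190 in wild type, 1080 ± 226 in heterozygotes and 685.3 ± 203 in the mutants (log2 fold change -1.15, SE 0.300, adjusted p = 0.129). Mycn had 0.40 (adjusted p = 0.680) and Gja5 -0.32 (adjusted p = 0.523). The list's median was -0.28 (adjusted p = 0.557). Its deviation was -0.30 and -0.46 in homozygous mutants 2 and 6 and 0.12 on arrays 8a and 9b, the arrays with the raised actin ratio, and -0.19, -0.18 and -0.28 in heterozygous 3, 4 and 8. Among 9 cardiac transcription factors Hand2 was lower (-1.06, adjusted p = 0.143) and Gata6 higher (0.85, adjusted p = 0.2) adjusted over the list alone, and none passed over all genes. That list's median was 0.09 (adjusted p = 0.557).

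Neural tube genes fell as a list. Their median log2 fold change was -0.63 and 13 of 15 were negative, with an adjusted p of 1.07e-05 and of 0.0109 with an estimated correlation. None passed over all genes and 4 were lower adjusted over the list alone. Tubb3, a tubulin of neurons, had a log2 fold change of -1.95 (SE 0.408, adjusted p = 0.0609). Hes5, a Notch target of neural progenitors, had -1.07 (SE 0.245, adjusted p = 0.0820), and Fabp7, of radial glia, had -1.33 (SE 0.321, adjusted p = 0.110). The list's deviation was -0.41, -0.53 and -0.76 in homozygous mutants 2, 6 and the pair 8a and 9b. With no filter on low signal the list's median was -0.10 (adjusted p = 0.000892, with 1.41e-07 to 0.0109 over all alternatives).

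Genes of gut and surface epithelium rose as a list, with a median of 0.45 and all 9 positive (adjusted p = 1.06e-06, and 0.00171 with an estimated correlation). Among the 10 splits of these replicates into equal groups, 2 gave a median as large in size. The real split was among them, and the other reached 0.506. Krt19 rose, the other 8 did not pass over all genes, and 2 were higher adjusted over the list alone, Krt19 and Krt18 (log2 fold change 1.30, adjusted p = 0.0800). The list's deviation was 0.87 and 0.38 in homozygous mutants 2 and 6, 0.43 on arrays 8a and 9b, and also 0.43 in heterozygous 4. The median was 0.83 among the replicates with high Afp and 0.42 among the others. With no filter on low signal it was 0.25 (adjusted p = 2.15e-05, with 1.4e-08 to 0.00171 over all alternatives).

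Cytosolic ribosomal protein genes had a median log2 fold change of 0.40 with 36 of 37 positive (adjusted p = 8.41e-09), and an adjusted p of 0.205 with an estimated correlation. None passed over all genes or adjusted over the list alone. Rpl13a had 0.63 (adjusted p = 0.144), Rps26 0.53 (adjusted p = 0.2) and Rps29 0.48 (adjusted p = 0.32). The list's deviation was 0.20 and 0.30 in homozygous mutants 2 and 6 and 0.83 on arrays 8a and 9b, and without those arrays the median was 0.21. After quantile normalization the median was 0.06 and the list did not pass (adjusted p = 0.101, with 8.78e-17 to 0.246 over all alternatives).

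**Figure D4:**
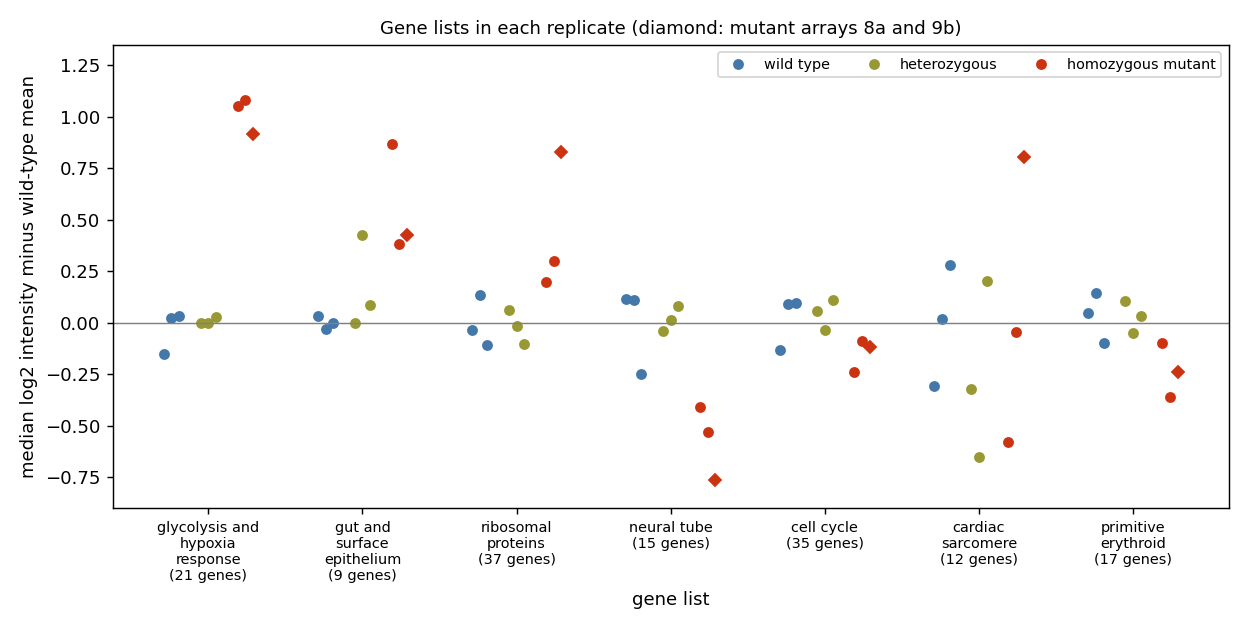
Median log2 intensity minus the wild-type mean over the genes of 7 lists (horizontal axis, number of tested genes in brackets) in each replicate, coloured by genotype, with homozygous mutant arrays 8a and 9b as a diamond. Glycolysis and hypoxia genes lie at 0.91 to 1.08 in the mutants and at -0.15 to 0.03 in the other replicates, and neural tube genes lie at -0.76 to -0.41 in the mutants. The ribosomal list, which does not pass after quantile normalization, and the sarcomere list reach 0.83 and 0.80 on arrays 8a and 9b.

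No other list passed in the main fit. Cell cycle passed in 5 of 22 alternatives (adjusted p = 0.00935 to 0.0343), oxidative phosphorylation in 3, each without 1 replicate (adjusted p = 0.00142 to 0.0333), and endothelium with the floor halved (adjusted p = 0.0185), calcium handling without homozygous mutant 2 (adjusted p = 0.0164) and mesenchyme with Afp as a block (adjusted p = 0.0377) in 1 each. With an estimated correlation none of these passed, with an adjusted p of 0.372, 0.274, 0.205, 0.537 and 0.427 in that order. The globins, which fill red cells, had log2 fold changes of 0.02 (Hba-a1, SE 0.411), 0.16 (Hbb-y, SE 0.262), -0.02 (Hba-x, SE 0.203) and 0.06 (Hbb-bh1, SE 0.270), and the 17 erythroid genes had a median of -0.21 (adjusted p = 0.194). Cell cycle genes had a median of -0.13 with 26 of 35 negative (adjusted p = 0.0589). Oxidative phosphorylation had 0.09 over 51 genes (adjusted p = 0.0996). The medians were 0.17 for mesenchyme (27 genes, adjusted p = 0.146), 0.17 for endothelium (11 genes, adjusted p = 0.160), 0.20 for Bmp and Tgf-beta signalling (15 genes, adjusted p = 0.165) and 0.26 for calcium handling and conduction (13 genes, adjusted p = 0.264). Hox paralogues 1 to 4 had -0.42 (adjusted p = 0.298), paralogues 5 to 8 had 0.00181 (adjusted p = 0.776) and paralogues 9 to 13 had -0.22 (adjusted p = 0.627). Heart field progenitors had 0.10 (7 genes, adjusted p = 0.488), neural crest 0.05 (9 genes, adjusted p = 0.504) and p53 targets -0.26 (5 genes, adjusted p = 0.640). Of the 11 somite genes (median -0.18, adjusted p = 0.504) 1 was lower adjusted over the list alone, Pax1 (under the floor in every mutant, so that -0.90 is a bound, adjusted p = 0.0909). Of the 15 liver and visceral endoderm genes (median -0.10 and mean 0.13, which differ in sign, adjusted p = 0.745) 1 was higher adjusted over the list alone, Apoe. Ier3 rose among 18 immediate early and heat shock genes (median 0.00603, adjusted p = 0.504), and adjusted over the list alone Ier3 was higher and Hsph1 lower (-0.85, adjusted p = 0.15). Nnat fell among 13 imprinted growth genes (median -0.02, adjusted p = 0.586), and 2 were lower adjusted over the list alone, Nnat and Cdkn1c. Lists too short to test had medians of 0.00258 (smooth muscle, 4 genes), -0.03 (myeloid and platelet, 4 genes), -0.23 (trophoblast and decidua, 1 gene) and 0.43 (sex-linked, 2 genes). The sex-linked list was fixed with Xist and genes of the Y chromosome together, so its median does not show the sex of the samples. Sex was not accounted for in any comparison.

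The count of 48 became 14 without wild type 5, 16 without wild type 7, 18 without homozygous mutant 2 and 27 without heterozygous 3, and 7 when only the compared groups were fitted. Ddit4, Krt19 and the brighter Slc2a3 probe set passed under every alternative, and Ier3 and Vldlr under all but the filter of at least 6 arrays above the floor, where they were not tested, while each other gene named by the rule lost its call under at least 1.

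Loss of a single allele was then compared with wild type. No probe set changed in the heterozygotes by limma's test, with 118 at an unadjusted p under 0.05 (88 higher, 30 lower) where chance gives 346.8. The smallest adjusted p was 1, and the groups did not overlap in 6.37% of probe sets against at most 10% by chance, a share that ties at the floor lower. The heterozygotes had 2682 ± 646 for Ddit4, 3201 ± 474 for Slc2a3 and 675.7 ± 137 for Krt19, each next to its wild-type mean. The log2 fold changes of smallest unadjusted p were 1.31 for Sh3bp1 (SE 0.272), 0.70 for Efhd2 (at least, since wild type lay under the floor), 0.75 for Rbmx, 1.42 for Anp32a and 0.47 for Fzd9. On the lower side they were -0.49 for Ebp, a sterol isomerase (a bound, since the heterozygotes lay under the floor), -0.71 for Hes6, -1.18 for Cops4, -1.28 for Josd2 and -2.21 for Kmt5c. Brighter probe sets of Efhd2 (-0.27), Anp32a (-0.17) and Josd2 (0.34) had the opposite sign, the brighter one of Hes6 had -0.27 and the other one of Kmt5c had -0.05. For Josd2 and Kmt5c only 1 of 3 heterozygous arrays exceeded the floor. All have an adjusted p of 1. Among heart genes Nppb had -0.47 (SE 0.300), Myl2 -0.59 (SE 0.624), Actc1 -0.18, Myl4 -0.21, Tnnc1 -0.44, Myh6 -0.36, Mycn 0.09 and Gja5 -0.10. The globins had 0.24 (Hba-a1), 0.11 (Hbb-y), 0.02 (Hba-x) and -0.12 (Hbb-bh1).

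Of the 24 lists 1 passed in the heterozygotes, oxidative phosphorylation, which holds subunits of the respiratory chain. Its median was -0.13 with 45 of 51 genes negative (adjusted p = 2.75e-07, and 0.000104 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. Uqcrq had a log2 fold change of -0.39 (SE 0.182), Uqcr10 -0.53 (SE 0.255) and Ndufa12 -0.38 (SE 0.211), each with an adjusted p of 1. The list's call ended with fry, which asks whether the genes move on balance without setting them against other genes (adjusted p = 0.965, with 2.26e-10 to 0.965 over all alternatives). Wild type 5 with heterozygous 3 and 4, and wild type 7 with heterozygous 8, formed clusters across genotypes, and within them the list's median was -0.058 and -0.192. With the clusters as a block it was -0.11 (adjusted p = 0.0104). The sarcomere list had a median of -0.28 (adjusted p = 0.0749) and passed in 10 of 23 alternatives (adjusted p = 0.000795 to 0.0467). With its estimated correlation of 0.514 its adjusted p was 0.895. Passing in 2 of 21 alternatives were the list reported lower in Nkx2-5 null hearts (0.0467 to 0.0489) and Hox paralogues 5 to 8 (0.00668 to 0.0104). Liver bud and visceral endoderm (0.0206) and gut and surface epithelium (0.0491) passed in 1 each. With an estimated correlation the adjusted p was 0.299 for the list reported lower and 0.895 for the others. The hypoxia list had 0.05 (adjusted p = 0.862).

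The homozygous mutants were also set against the heterozygotes, which share 1 functional allele, to ask what the loss of the remaining allele adds. The mutants were again higher for hypoxia genes: Ddit4 rose 9.06-fold (log2 fold change 3.18, SE 0.209, limma adjusted p = 6.28e-05), Slc2a3 4.01-fold at its brighter probe set (adjusted p = 0.000226), P4ha2 3.0-fold (adjusted p = 0.00765) and Adm at least 3.41-fold (adjusted p = 0.00437). Krt19 rose 5.64-fold (adjusted p = 0.00097), Ier3 at least 6.72-fold (adjusted p = 0.00056) and Apoe at least 4.6-fold (adjusted p = 0.0272). The other probe sets of Slc2a3 (log2 fold change 1.79, adjusted p = 0.0563) and Apoe (2.22, adjusted p = 0.0813) did not pass. Hcfc1 fell at least 3.83-fold, from 2010 ± 171 to under the floor (adjusted p = 0.00465). Gpc1, a cell surface proteoglycan, fell by 1.38 on the log2 scale at 1 probe set (adjusted p = 0.0129), while its brighter probe set had -0.18 (adjusted p = 0.812). Cenpb, which binds centromeric DNA, fell by 1.43 (adjusted p = 0.0433) and Mapk7, a mitogen-activated kinase, fell by 1.38 (adjusted p = 0.0486). Nnat fell by 0.81 (adjusted p = 0.0244). The mutant arrays are those of the first comparison, so the 2 comparisons are not independent.

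In all 80 probe sets changed, 51 higher and 29 lower, with 1090 at an unadjusted p under 0.05, and for 34 named genes higher and 17 lower. With each array scaled to its 75th percentile the split was 65 higher and 19 lower. In all 80 the groups did not overlap, as in 22.6% of tested probe sets against at most 10% by chance. Of the 21 hypoxia genes 8 rose and none fell (median 0.86, adjusted p = 3.66e-30, and 9.85e-22 with an estimated correlation), and 14 were higher adjusted over the list alone. Of the 15 neural tube genes 1 fell, Hes5 (from 2950 ± 291 to 1273 ± 413, adjusted p = 0.0335), and 6 were lower adjusted over the list alone. The neural list had a median of -0.52 (adjusted p = 0.000401, and 0.0452 with an estimated correlation). Pax1, of the sclerotome, fell to under the floor in every mutant, by at least 1.07 on the log2 scale (adjusted p = 0.0335). The gut and surface epithelium list had 0.23 (adjusted p = 0.000906, and 0.0452 with an estimated correlation), with 1 of 9 genes higher over all genes and 2 adjusted over the list alone. Its median was reached in size by 3 of the 10 splits of these replicates, the real one among them. Without heterozygous 3 and without heterozygous 8 the neural median was -0.85 and -0.30, and without heterozygous 4 and without homozygous mutant 2 the gut median was 0.39 and 0.10. Without a filter the medians were -0.04 and 0.11.

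Oxidative phosphorylation genes were higher as a list, with a median of 0.23 and 43 of 51 positive (adjusted p = 1.42e-05, and 0.00145 with an estimated correlation), and 0 of them passed over all genes while 2 did adjusted over the list alone. Those were Ndufv3 (log2 fold change 1.12, adjusted p = 0.0607) and Cox7a2l (1.13, adjusted p = 0.0644), whose other probe set had -0.32 (SE 0.88, adjusted p = 0.89), and Ndufs4 had 0.56. The call ended with fry (adjusted p = 0.176, with 1.54e-08 to 0.176 over all alternatives). The deviation of that list from wild type was -0.04 and -0.01 in homozygous mutants 2 and 6 and 0.37 on arrays 8a and 9b, and without those arrays the median against the heterozygotes was 0.08. Ribosomal protein genes had a median of 0.43 (adjusted p = 2.22e-08), with an adjusted p of 0.2 with an estimated correlation, and 1 rose, Rpl13a (log2 fold change 0.86, adjusted p = 0.0343). Its median was 0.24 without arrays 8a and 9b and 0.10 after quantile normalization. Cell cycle genes had a median of -0.13 with 28 of 35 negative (adjusted p = 0.0451), and an adjusted p of 0.34 with an estimated correlation. The cell cycle call ended without heterozygous 3 (adjusted p = 0.0588), heterozygous 8 (0.259) or homozygous mutant 2 (0.125), with 0.00457 to 0.34 over all alternatives. Its members Mcm2 (-0.57), Ccne1 (-0.79) and Rrm2 (-0.58 at its brightest probe set) did not pass, while another Rrm2 probe set fell by 1.01 (adjusted p = 0.0119). None of the heart lists passed in the main fit, while without homozygous mutant 2 the sarcomere list (adjusted p = 0.0404) and calcium handling (adjusted p = 0.0248) did, and with fry the cardiac transcription factors (adjusted p = 0.00384). With an estimated correlation and all replicates in the fit the adjusted p was 0.872 for sarcomere, 0.628 for calcium handling and 0.628 for the cardiac transcription factors. Nppb had -0.68 (SE 0.300, adjusted p = 0.300) and Actc1 0.08.

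The count of 80 became 14 without heterozygous 3, 15 without heterozygous 4, 41 without heterozygous 8, 32 without homozygous mutant 2 and 47 without wild type 5, 40 when only the compared groups were fitted, and 708 with array weights. Ddit4, Krt19, Hcfc1 and the brighter Slc2a3 probe set passed under every alternative, and Ier3 under all but the filter of at least 6 arrays above the floor, where it was not tested.

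A last comparison asked which genes do not follow the number of mutant alleles in equal steps, by setting the heterozygotes against the midpoint of the other genotypes. Ddit4 was the only gene that passed, lying below the midpoint by a log2 value of -1.51 (SE 0.181, limma adjusted p = 0.0296), with 546 probe sets at an unadjusted p under 0.05. Its heterozygous mean of 2682 stood beside 2348 in wild type and 23880 in the homozygous mutants. Slc2a3 (-0.96, adjusted p = 0.0583), Pgm1, a phosphoglucomutase (-0.80, adjusted p = 0.0583), Ier3 (-1.37 with wild type and heterozygotes both set to the floor, which leaves its true value open in both directions, adjusted p = 0.0792) and Anxa2 (-1.07, adjusted p = 0.0792) lay below the midpoint without passing. The other Slc2a3 probe set had -0.58 (adjusted p = 0.724). Above it lay Hcfc1 (at least 1.21, since every mutant lay under the floor, adjusted p = 0.11), Gpc1 (0.999, adjusted p = 0.122), Snx17 (0.78), Rcc1 (0.71) and Bdkrb1 (at least 1.05 for the same reason), none past the threshold, and the brighter probe set of Gpc1 had -0.00949. The call of Ddit4 ended without wild type 1, 5 or 7, heterozygous 3 or 4, or homozygous mutant 2 or 9b, without arrays 8a and 9b and with no filter, with a log2 value of -1.61 to -1.29 and an adjusted p of 0.0534 to 0.134 in those fits, and 0.00422 to 0.134 over all alternatives. Of the 24 lists 4 passed against the midpoint: glycolysis and hypoxia lay below it (median -0.40, adjusted p = 2.58e-17, 1.89e-12 with an estimated correlation), as did oxidative phosphorylation (-0.17, adjusted p = 5.21e-08, 2.76e-05 with an estimated correlation). Without arrays 8a and 9b the oxidative phosphorylation median was -0.11 (adjusted p = 3.03e-05), and its call ended with fry (adjusted p = 0.417, with 6.51e-11 to 0.417 over all alternatives). Ribosomal protein genes had -0.22 (adjusted p = 4.16e-06, and adjusted p = 0.429 with an estimated correlation), and neural tube genes had 0.34 (adjusted p = 0.0263, and adjusted p = 0.337 with an estimated correlation). The ribosomal median was -0.15 without arrays 8a and 9b and -0.07 after quantile normalization, where the call ended (adjusted p = 0.0706, with 1.52e-10 to 0.61 over all alternatives). The neural call ended without wild type 5 (adjusted p = 0.0518), wild type 7 (0.188), heterozygous 8 (0.367), homozygous mutant 6 (0.055) or array 8a (0.0602), without arrays 8a and 9b (0.0937), with no filter (0.194) and with fry (0.166), with 0.00243 to 0.367 over all alternatives.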

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

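Of the tests below, the splits of the samples, all tests of arrays 8a and 9b, all tests of the glycolysis and hypoxia list, the ribosomal list without those arrays, and its tests against the nearest 5 genes and after quantile normalization were chosen after the result was seen, and the test against genes about as bright was chosen before.

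Control probe sets that no comparison uses stood out on homozygous mutant arrays 8a and 9b, above the highest wild-type array of their type. BioB was 3950 on array 8a and 4531 on array 9b, against at most 1342 and 2320 in wild type, and the Cre spike-in was 112385 and 114453, against at most 37632.8 and 81255. The 3' to 5' ratio of actin was 2.5 and 2.28, against at most 1.41 and 1.4, and that of Gapdh was 1.33 and 1.21, against at most 0.929 and 1.

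Why arrays 8a and 9b stood apart was weighed first. A wrong genotype label could not be decided. The hypoxia list's deviation there was 0.914, against 1.05 and 1.08 in the other homozygous mutants. In all wild-type and heterozygous replicates it was -0.152 to 0.0333. After quantile normalization it was 0.488, against 1.07 in both other mutants and -0.0266 to 0.0456 in the rest. In this list the arrays resembled the other mutants, but its rise was found in the same comparison and may not be due to genotype. The list reported lower in Nkx2-5 null hearts went the other way, at 0.122 against -0.295 and -0.457 in homozygous mutants 2 and 6. Spearman correlations across tested probe sets, with the mean over arrays removed, showed no likeness to the other mutants either. Array 8a had 0.011 and -0.014 with homozygous mutants 2 and 6, and -0.48 to 0.001 with wild-type and heterozygous arrays. Array 9b had -0.017 and -0.11, and -0.37 to 0.0091. Homozygous mutants 2 and 6 had 0.38 on type a and 0.2 on type b with each other. RNA or labelled product shortened towards the 3' end stays open, because the ratio of Gapdh on array 8a, 1.33, lay above all other arrays together with that of actin. Less sample RNA against a fixed amount of spike-in also stays open and may act together with it, since all 4 spike-ins were above every other array of their type, by at least 1.79-fold over the median. On array 8a the excess was not confined to spike-ins: the brightest probe set outside the controls had 151953, against at most 64187.9 on the others. On array 9b it had 135753, against at most 134088. No biological explanation was tested, as the other homozygous mutants did not show these signals.

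The joint rise of glycolysis and hypoxia genes, Ddit4, Slc2a3, Adm and Pdk1 among them, was weighed next. Arrays 8a and 9b alone are argued against, since the list's median without them was 1.06, and the authors' scaling is too, since it was 0.91 after quantile normalization. A difference in the portion of the embryo taken that Afp follows is argued against as the whole cause, because the smaller median within replicates of like Afp was 0.851. The replicates with high Afp were only 1 of each genotype. Among high and low Afp alike, neural tube genes had medians of -0.533 and -0.643, and gut genes 0.832 and 0.417. Differences in the portion taken that Afp does not follow therefore stay open. Handling of the embryos before RNA was taken cannot be told apart from genotype: the immediate early and heat shock list had an adjusted p of 0.504, although Ier3 rose, and how each embryo was handled is not known. An effect of genotype and a difference in stage between genotypes were not tested apart from handling and stay open. The clusters of wild-type and heterozygous replicates held no homozygous mutant. A structure of the samples like the one behind them therefore also cannot be told apart from genotype here.

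The rise of ribosomal protein genes in the homozygous mutants was weighed last. The list's median was 0.212 without arrays 8a and 9b (adjusted p = 0.000153 at the preset correlation of 0.01) and 0.397 with them. With all arrays in the fit the list did not pass with fry (adjusted p = 0.246). Nor did it pass at its correlation of 0.305, which was estimated without arrays 8a and 9b (adjusted p = 0.205). The fit without the arrays was not repeated in those ways, so these arrays stay open as its whole cause. A scale that depends on intensity is argued against as the whole cause, because genes about as bright rose less. Among 10000 random lists of such genes the median was 0.0716 and the highest 0.263, at a median level gap of -0.235 on the log2 scale. With the nearest 5 genes, at a gap of -0.0191, the median rose to 0.0998 and the highest to 0.321. The list lay at percentile 100. The random lists were drawn gene by gene, without the list's estimated correlation of 0.305. Their spread is therefore too narrow, and the percentile overstates the contrast. As a part of the cause such a scale stays open. Quantile normalization, which corrects such a scale, ended the call by taking the list's median to 0.0592 (adjusted p = 0.101). The middle 95% of the random lists of the 25 nearest genes, 0.0137 to 0.16 before, then spanned -0.154 to 0.012. Among the 50 brightest genes the ribosomal ones had a median of 0.479 on type a (21 genes, against 0.0518 in the 29 others) and 0.185 on type b (10 genes, against 0.0689 in the 40 others), and a difference in RNA quality between replicates and an effect of genotype also stay open, neither tested further.

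The count of 48 probe sets between homozygous mutant and wild type was reached in 1 of the 10 splits of the 6 replicates, the real one, and the highest other split gave 0. Between homozygous mutant and heterozygous it was 80, as large in 1 of 10, with 0 as the highest other. Between heterozygous and wild type all 10 splits gave at least the real 0. There the split that sets wild type 5 with heterozygous 3 and 4 against wild type 1, wild type 7 and heterozygous 8 gave 125, which points to a structure of the samples other than genotype, and with the clusters as a block the count was 0. For gene lists 6 of 10 splits gave as many as the real 4 for homozygous mutant against wild type (highest other 8), 8 as many as the real 1 for heterozygous against wild type (highest other 3) and 5 as many as the real 6 for homozygous mutant against heterozygous (highest other 9). For the hypoxia list itself, the median of 0.893 stood against 0.462 as the highest size in the other splits, for the neural list -0.634 against 0.459, for the ribosomal list 0.397 against 0.388 and for the gut list 0.447 against 0.506. For the oxidative phosphorylation list in the heterozygotes the median of -0.134 stood against 0.135, and 2 of the 10 splits were as large. For homozygous mutant against heterozygous the values were 0.855 against 0.417 (hypoxia), -0.524 against 0.442 (neural), 0.432 against 0.402 (ribosomal), 0.229 against 0.194 (oxidative phosphorylation), 0.225 against 0.472 (gut) and -0.131 against 0.148 (cell cycle). With 10 splits no share under 0.05 can be reached. For the heterozygotes against the midpoint 15 of 100 splits gave as many as the real 1, with 199 as the highest, and for lists 56 of 100 gave as many as the real 4, with 8 as the highest, so chance is not excluded for either count.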

How the results depend on the processing

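The fits without arrays 8a and 9b and with blocks for Afp or for clusters, and the alternatives for lists in homozygous mutant against heterozygous and against the midpoint and for genes named outside homozygous mutant against wild type, were chosen after the data were seen. The 36 calls of named probe sets, some of them called in more than 1 comparison, kept their direction in all 819 alternative values, and 610 were still past it while 209 were not, 130 of these among the 360 values with 1 replicate left out. Hypoxia, neural and gut lists passed in all 22 alternatives against wild type, with medians of 0.713 to 1.06, -0.757 to -0.103 and 0.252 to 0.668, and the ribosomal list in 19. Signal over background limits the folds of values next to the floor, which are understated, and the cause of each shift below was not tested unless it is given. No paired test was possible, because the genotypes share only the number 8, and the midpoint needs all groups, so it has no fit on only some.

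For homozygous mutant against wild type the 48 probe sets became 19 with no filter, which tests more probe sets, and 7 on only the groups compared, which leaves fewer arrays for the spread. They became 14 to 61 with 1 replicate left out, and 38 to 71 under every other alternative; 39 of 55 were shared without arrays 8a and 9b. Its 4 lists became 3 after quantile normalization, with an estimated correlation and with fry, 6 with the floor halved, 5 with no filter, with Afp as a block and with all probe sets of a gene kept, and 4 to 6 with 1 replicate left out. For homozygous mutant against heterozygous the 80 became 45 with no filter, 40 on only the groups compared, 708 with array weights and 14 to 99 with 1 replicate left out, and its 6 lists became 4 with an estimated correlation and with fry, and 5 to 7 otherwise. For heterozygous against wild type the 0 stayed 0 except for 1 without wild type 7 and without heterozygous 8 (0 to 1). Its 1 list became 3 after quantile normalization, with the floor doubled and with clusters as a block, 2 without arrays 8a and 9b, with Afp as a block and with all probe sets of a gene kept, 0 with fry, and 1 to 3 with 1 replicate left out. Against the midpoint the 1 probe set became 3 at the common 75th percentile, above the floor on at least 6 arrays and without trend, 4 with the floor doubled, 5 with no filter, 141 with array weights, 0 without arrays 8a and 9b, and 0 to 3 with 1 replicate left out. Its 4 lists became 2 with an estimated correlation and with fry, and 3 to 6 with 1 replicate left out.

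Genes of heart and blood that had not passed changed sign in the log2 fold change of homozygous mutant against wild type. After quantile normalization Myl4 had -0.128 and Hba-a1 -0.195. With array weights Myl4 had -0.211, Tnnc1 -0.00736, Myh6 -0.21, Hba-a1 -0.388 and Hbb-y -0.0305. Without arrays 8a and 9b they had -0.315, -0.0856, -0.298, -0.431 and -0.0901. With 1 replicate left out the ranges were -0.274 to 0.108 for Actc1, -0.315 to 0.408 for Myl4, -0.0856 to 0.459 for Tnnc1, -0.298 to 0.432 for Myh6, -1.67 to 0.0285 for Myl2, -0.431 to 0.45 for Hba-a1, -0.0901 to 0.358 for Hbb-y, -0.172 to 0.147 for Hba-x and -0.207 to 0.327 for Hbb-bh1.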

Other observations

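The genes in the first paragraph and the clusters in the second were chosen after their values were seen. In the homozygous mutants against wild type, Pgm1, a phosphoglucomutase that links glycogen and glycolysis, rose from 6198 ± 152 (SD, n = 3) to 15360 ± 760 (log2 fold change 1.31, limma adjusted p = 0.000629), with 5638 ± 671 in the heterozygotes. Asns, which makes asparagine and is induced by amino acid shortage, rose by a log2 fold change of 1.32 (adjusted p = 0.0111), and Upp1, a uridine phosphorylase, by 1.34 (adjusted p = 0.0190). Anxa2, a membrane-binding annexin, rose at a probe set on each array type, by 1.16 on type a (adjusted p = 0.0220) and 1.46 on type b (adjusted p = 0.0105). Ctsl, a lysosomal protease, rose at both of its probe sets, by 1.18 (adjusted p = 0.00944) and 1.14 (adjusted p = 0.0317). Igfbp2, a binding protein of insulin-like growth factors, rose by 0.96 (adjusted p = 0.0190). Cdk2ap1, an inhibitor of Cdk2, had -0.78 at the probe set that passed (adjusted p = 0.0440) and -0.81 at the other (adjusted p = 0.0505).

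Replicates of different genotypes resembled each other in pairs across genes, which are not independent replicates. After the mean over all arrays was removed, the Spearman correlation of wild type 5 with heterozygous 3 was 0.55 on type a and 0.34 on type b, and that of wild type 7 with heterozygous 8 was 0.49 and 0.54. Heterozygous 3 and 4 had 0.56 and 0.47. Over the 2089 probe sets under the floor on type a the values were 0.37 for wild type 5 with heterozygous 3 and 0.42 for wild type 7 with heterozygous 8, and over the 2708 on type b they were 0.032 and 0.28. Neither wild type 1 nor a homozygous mutant lay in these clusters, so within them no mutant can be compared with wild type. Wild type 1 with homozygous mutant 2, both with high Afp, had 0.23 on type b and 0.33 under the floor there, but 0.043 and -0.0073 on type a, and heterozygous 8 with homozygous mutant 6 had 0.3 under the floor on type a and -0.13 on type b. The hypoxia list's deviation was -0.152 in wild type 1. On type a the 5' signal of 18S ribosomal RNA was 1774, 807.6 and 3544 in wild type 1, heterozygous 4 and homozygous mutant 2, the replicates with high Afp, and at most 264.4 in the others. On type b it was 2506, 394.5 and 4561 there, with 542 in homozygous mutant 6 and 932.3 in 9b, where Afp was low.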
